A study of Mus musculus with 11 samples.

How the data were processed

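The series holds 11 mouse samples, each the single member of its group, so no replicate spread could be computed and no p-values or SDs are given. Chromatin was profiled in 3 cell populations. The first was Cited1-RFP+ cap mesenchyme, the nephron progenitors that give rise to the filtering units of the kidney, sorted by fluorescence from E18.5 kidneys of Cited1nuc-TagRFP-T mice. The second was Hoxb7-GFP+ ureteric epithelium, the branching tube that becomes the collecting duct system, sorted from E15.5 kidneys of Hoxb7myr-Venus/+ mice. The third was the mouse embryonic stem cell line E14, at passage 15. Per the labels, native (unfixed) chromatin was digested with micrococcal nuclease and precipitated for H3K4me3, a mark of promoters open to transcription, or for H3K27me3, the mark left by Polycomb repressive complexes. RNA came from metanephric mesenchyme and ureteric bud dissected by hand from wild-type C57BL/6 embryos at E11.5, with stranded libraries of total RNA.

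The 6 peak lists were used as deposited. Per the submitters' processing notes, reads were aligned with Bowtie2 and peaks were called with MACS on mm10, while the RNA was processed with TopHat, Cufflinks and Cuffdiff. Versions, settings, the control set against each ChIP library and the number of libraries behind each list or column were not given in the sources used here. Each peak carries a score, the authors' own caller value as deposited. What it measures was not given in the sources used here. It was used to rank or filter peaks within a list, and a common minimum across lists was tried only as an alternative. The 3 input libraries were not analysed here. RNA levels were the deposited FPKM values of the authors' Cuffdiff table, 1 column for metanephric mesenchyme and 1 for ureteric bud. FPKM are fragments scaled by transcript length and by the fragments mapped in the library, so they are relative to everything mapped.

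The RNA table held 138486 transcripts in 41804 loci, and 89.6% of the transcripts were paired with a gene, 106224 by accession and 17901 by locus position, leaving 14361 unpaired. Transcripts were summed per gene. Of the 138486 transcripts, 5290 had no reference, and these held 93.6% of the FPKM total in metanephric mesenchyme and 93.9% in ureteric bud. The 20 most abundant of them had a median length of 54 bp, and they were left out of every comparison. Protein-coding genes summed to 136771 FPKM in metanephric mesenchyme and 204821 in ureteric bud. Read counts were not used here, and depth was judged only from the smallest values: the lowest FPKM times transcript length in kb was 0.0302 in metanephric mesenchyme and 0.0345 in ureteric bud, which places both libraries at a similar depth on that measure. The number of reads behind a peak list is unknown.

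Gene positions (mm10, counted from 1) were those of 34614 genes, 21887 protein-coding and 12727 long noncoding. Strand was inferred from the order of loci in the RNA table, where all 1245 antisense transcripts lay in a block opposite to their host gene and all 19557 transcripts sharing a splice junction lay in the same block as their reference. The inferred start of 9877 genes longer than 20 kb carried H3K4me3 in 76.7% of cases in cap mesenchyme, against 6.51% at the opposite end. Both ends were used for the 3677 genes left without a strand. A gene has 1 start here, the outermost, so promoters inside a gene can be missed. Among 3581 genes at 10 FPKM or more in metanephric mesenchyme, 94.8% had H3K4me3 in cap mesenchyme at that start and 99.7% within 1 kb of the gene body.

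A promoter was the start plus and minus 1 kb, and a mark was called present with at least 1 bp of a peak. This gives 4 states, H3K4me3 only, both marks, H3K27me3 only and neither. The state with both marks is often called bivalent in stem cells, but sorted populations are mixtures and both marks at a promoter here need not lie in the same cell. Shares carry 95% exact binomial (Clopper-Pearson) intervals, which cover counting error over genes only. Peak sets were compared by overlap of at least 1 bp and by the Jaccard index of covered bases, beside 100 shuffles of the peaks along each chromosome.

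RNA differences are log2(FPKM + 1) in metanephric mesenchyme minus ureteric bud, a scale that understates the change of low genes. A gene was counted as 4-fold different at a difference of 2 with at least 2 FPKM in the higher library. List medians used members at 1 FPKM or more in either library. They are given with 95% order-statistic intervals over genes, or with the range for lists under 6 members. Each median was also placed as a percentile among 10000 random gene lists of the same size, which describes these 2 libraries only. The random lists were matched on gene type (protein-coding or long noncoding) and mean expression. The 28 gene lists, with 550 different genes, were fixed before the data were examined, as were the comparisons and most alternatives: nephron progenitor, ureteric bud, epithelial, mesenchymal and matrix, renal stroma, early differentiating nephron, podocyte, mature tubule transport, endothelial, red cell and blood, neuron and neural crest, pluripotency, transcription factors of other lineages, germ cell, the HoxA, HoxB, HoxC and HoxD clusters, GDNF, RET and FGF signalling, Wnt signalling, BMP and TGF-beta signalling, Notch signalling, retinoic acid, glycolysis, cell cycle, writers and erasers of H3K4 and H3K27 methylation, housekeeping genes and long noncoding RNAs.

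Genes are named by a rule fixed at the same time. For RNA it takes the 8 genes with the largest log2 difference in each direction among genes with a symbol and at least 2 FPKM in the higher library, then up to 4 members per described list with the largest difference in the direction of the list median and up to 2 with the largest opposite difference, and Six2, Cited1, Ret, Wnt11, Gdnf, Hoxb7, Pou5f1, Nanog and Sox2 in every data type as checks of the labels. For chromatin it takes up to 4 members per described list whose state differs between the cell types compared, those with the largest RNA difference in size, or for comparisons with stem cells those with the widest stem cell peak over the start. It also takes the 5 genes with the largest RNA difference in each direction among those with a mark in one kidney population only, and the gene at each of the 5 widest peaks of each list. Other genes are said to be chosen after their values were seen. Some genes the rule takes are not reported here.

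Alternatives tried were promoter windows of 500 and 2500 bp on each side, the upper 50% of each list by score, equal list lengths per mark, reciprocal overlap of at least 50%, H3K27me3 peaks merged within 3 kb, H3K27me3 over at least 50% of the window, genes in the RNA table only, the most abundant transcript per gene, pseudocounts of 0.1 and 0.5, no filter on low values, a minimum of 5 FPKM, transcripts with status OK only, random lists without matching, and rescaling of the libraries to the same median. Chosen after seeing the data were both ends of every gene as promoter, a score of at least 50 in every list, leaving out the Hoxb3 to Hoxb9 genes, and leaving out the endothelial, blood and neural crest lists. The code was tested on simulated data. All 396 promoter windows equalled a base by base count, and the 55 shared peaks equalled a direct count. For the RNA lists, simulated on 11599 genes, 3 of 100 unchanged lists fell outside the middle 95%, and 10 of 10 lists of 20 genes shifted by a log2 of 1 lay above it. The simulated lists were random, with differences drawn independently per gene and unrelated to expression. They therefore tested neither the expression matching nor lists of genes that vary together, such as a Hox cluster. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.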

Results

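H3K4me3 and H3K27me3 were mapped in cap mesenchyme, ureteric epithelium and E14 embryonic stem cells, giving 6 peak lists, and RNA was measured in metanephric mesenchyme and ureteric bud. Each group held 1 sample, so no difference below has a replicate check. The H3K4me3 lists held 32992 peaks in cap mesenchyme, 23958 in ureteric epithelium and 67022 in stem cells, with median widths of 1312, 1547 and 1481 bp. The H3K27me3 lists held 108394, 144362 and 12879 peaks, with median widths of 195, 281 and 657 bp. The lowest score kept by the authors was 50 in all H3K4me3 lists, but 40, 30 and 40 in the H3K27me3 lists, and whether these bounds are comparable between lists is unknown. Of the genes with an RNA value, 10492 reached 1 FPKM in metanephric mesenchyme and 10842 in ureteric bud. The RNA tissue was taken at E11.5, earlier than the sorted cells, which came from E18.5 (cap mesenchyme) and E15.5 (ureteric epithelium).

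Genes with known sites of expression served as a check of the labels. Six2, a transcription factor that keeps nephron progenitors undifferentiated (chromosome 17: 85662736 to 85688254, mm10), was at 55.5 FPKM in metanephric mesenchyme and 1.58 in ureteric bud. Its promoter carried H3K4me3 only in cap mesenchyme and both marks in ureteric epithelium and stem cells. Gdnf, the ligand that draws out the ureteric bud, was at 10.8 and 0.0752 FPKM, while its receptor Ret (chromosome 6: 118151748 to 118197744) was at 0.341 and 72.8 FPKM. Wnt11, a ureteric tip gene, was at 1.31 and 32.3 FPKM with both marks in all 3 populations, and Hoxb7 was at 9.95 and 75.8 FPKM. Cited1, whose reporter was used to sort the progenitors, was at 2.78 FPKM in metanephric mesenchyme and 8.34 in ureteric bud, and carried H3K4me3 only in both kidney populations. Among pluripotency factors, Pou5f1, Nanog and Sox2 had H3K4me3 only in stem cells. In cap mesenchyme Pou5f1 had neither mark, Nanog had H3K27me3 only and Sox2 had both. Pou5f1 and Nanog RNA was listed at 0 in both tissues.

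The first comparison asked where each mark lay and how far the peaks were shared between populations. The widest H3K4me3 peaks of cap mesenchyme lay over Hox clusters and Nr2f2, a nuclear receptor of mesenchyme. They spanned 48.2 kb from Hoxa3 to Hoxa11 (chromosome 6: 52202266 to 52250507), 45.5 kb at Hoxb (chromosome 11: 96275979 to 96321438), 35.5 kb from Hoxc11 to Hoxc9 (chromosome 15: 102953232 to 102988721), 29.2 kb at Nr2f2 and 26.8 kb from Hoxd12 to Hoxd9. In ureteric epithelium they included Hoxa9 and Hoxa10 (22.5 kb), Gata3 (22.4 kb; chromosome 2: 9868564 to 9891003), Hoxd3 and Hoxd4 (20.9 kb), and Pax2 (19.9 kb), where Gata3 and Pax2 are regulators of ureteric growth. In stem cells they were at Trim71, Tet1, Jarid2, Ctbp2 and Esrrb, between 45.4 and 37.3 kb. The widest H3K27me3 peaks with a gene were at Six3 (13.9 kb) in cap mesenchyme, at Fcgr3 (22.6 kb), Foxf1 (22.3 kb), the predicted genes Gm40363, Gm52861 and Gm52862 (20.5 kb) and Onecut3 (19.2 kb) in ureteric epithelium, and at Hoxa9 and Hoxa10 (17.8 kb) and Pax2 (16.3 kb) in stem cells. The widest peak in both kidney H3K27me3 lists, 25.4 kb in cap mesenchyme and 87.8 kb in ureteric epithelium, lay in the same stretch of chromosome 8. That stretch held no protein-coding or long noncoding gene, and other gene types were not among the positions used.

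H3K4me3 peaks of the kidney populations were shared more than their H3K27me3 peaks. Of the ureteric H3K4me3 peaks, 87.2% overlapped a cap mesenchyme peak, and of the cap mesenchyme peaks 61.7% overlapped a ureteric one and 72.2% a stem cell one. The Jaccard index of covered bases was 0.630 between cap mesenchyme and ureteric epithelium (0.0098 after shuffling) and 0.301 between cap mesenchyme and stem cells (0.0160). For H3K27me3 it was 0.170 (0.0070) and 0.130 (0.0034). Of the H3K27me3 peaks, 38.0% of those in cap mesenchyme overlapped a ureteric peak and 7.10% a stem cell peak. The shares depend on list length and on the overlap rule, and the 7.10% became 1.27% with reciprocal overlap of at least 50% and 32.2% at equal list length. From the side of stem cells it was the reverse, as 34.2% of their H3K4me3 peaks and 36.1% of their H3K27me3 peaks overlapped one of cap mesenchyme, and 27.9% and 45.8% one of ureteric epithelium. H3K4me3 peaks lay at promoters in 43.7%, 56.0% and 24.6% of cases in cap mesenchyme, ureteric epithelium and stem cells, and H3K27me3 peaks in 4.11%, 2.97% and 32.6%.

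The next comparison asked how promoters were marked in each population and what became of promoters that carried both marks in stem cells. Of 34614 genes, 15540 had H3K4me3 only in cap mesenchyme, 1731 both marks, 801 H3K27me3 only and 16542 neither. The counts were 14031, 1849, 1704 and 17030 in ureteric epithelium, and 16147, 3135, 257 and 15075 in stem cells. Thus 92.4% of promoters with H3K27me3 also had H3K4me3 in stem cells (95% exact binomial interval 91.5 to 93.3), 68.4% in cap mesenchyme (66.5 to 70.2) and 52.0% in ureteric epithelium (50.4 to 53.7). This order depended on list length, as at equal length per mark, a comparison made only after the data were seen, the shares were 64.6%, 76.1% and 57.4%. Counts with H3K27me3 moved most with the calling rule. With H3K27me3 over at least 50% of the window, both marks were found at 602 genes in cap mesenchyme, 771 in ureteric epithelium and 1358 in stem cells.

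**Figure D1:**
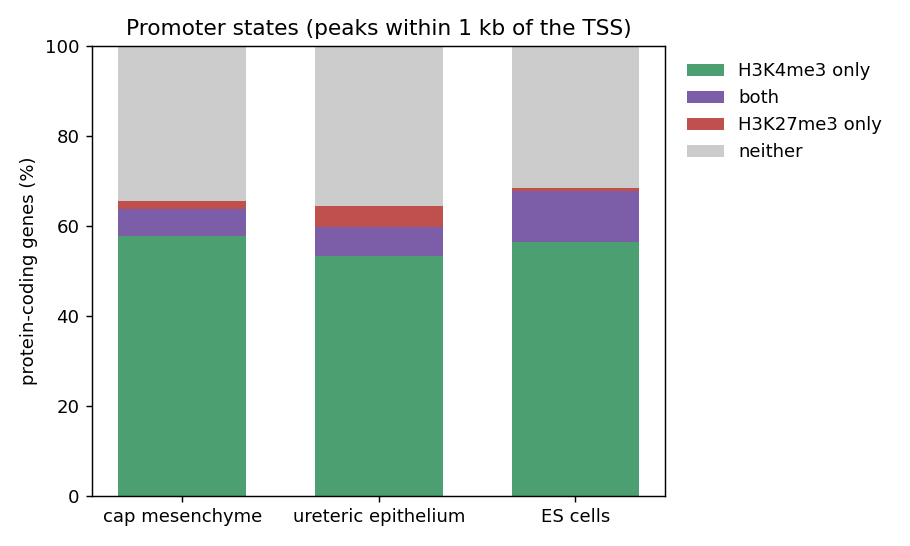
Share of protein-coding genes, in percent, with H3K4me3 only, both marks, H3K27me3 only or neither at the start plus and minus 1 kb, per population (1 sample each). Of 21887 protein-coding genes, both marks were found at 2444 (11.2%) in stem cells, 1296 (5.92%) in cap mesenchyme and 1433 (6.55%) in ureteric epithelium.

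Nephron progenitor genes with both marks in stem cells mostly carried H3K4me3 only in cap mesenchyme. This held for 12 of 14, among them Six2, Osr1, Wt1 and Hoxa11, transcription factors of the early kidney, while in ureteric epithelium 7 of the 14 kept both marks. HoxA genes leaned the same way, with H3K4me3 only at 10 of 11 in cap mesenchyme and 5 of 11 in ureteric epithelium, and so did renal stroma genes (9 and 2 of 15) and members of GDNF, RET and FGF signalling (13 and 8 of 14). These lists share some members, such as Hoxa11 and Gdnf, all genes with both marks in stem cells leaned this way too (below), and no list was tested against them. Early differentiating nephron genes went the other way, with both marks at 10 of 15 in cap mesenchyme and 5 of 15 in ureteric epithelium. Transcription factors of other lineages, such as Pax6, Nkx2-1 and Otx2 of the nervous system, kept H3K27me3. Of the 38 with both marks in stem cells, 27 had both and 11 had H3K27me3 only in cap mesenchyme, against 9 and 28 in ureteric epithelium. Over all 3135 genes, 55.4% had H3K4me3 only in cap mesenchyme (53.6 to 57.1), 38.6% both marks, 3.73% H3K27me3 only and 2.26% neither. In ureteric epithelium the shares were 41.5% (39.8 to 43.2), 37.9%, 14.8% (13.6 to 16.1) and 5.81%. H3K4me3 only in both kidney populations was found at 1118 genes and both marks in both at 677.

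Cap mesenchyme and ureteric epithelium were then compared promoter by promoter, to ask which regulators differ between the 2 lineages of the kidney. H3K27me3 in ureteric epithelium and not in cap mesenchyme was found at the progenitor genes Six2, Osr1, Wt1, Hoxa11 and Hoxd11. The same was seen at 7 of 17 renal stroma genes, including Aldh1a2, which makes retinoic acid, Foxc1, Meis1 and Nr2f1, and at 8 of 23 mesenchymal genes, including Col1a1, Snai2, Cdh2 and Prrx1. Some of these calls rest on peaks that are weak within their own list, as the best ureteric score at Aldh1a2 (35.1), Meis1 (32.9), Snai2 (36.8), Cdh2 (30.9) and Col1a1 (33.8) lay under the median of 39.3 of the ureteric H3K27me3 list. A score of at least 50 in every list was a setting chosen after seeing the data that takes scores as comparable between lists. With it, 4 of the 7 stroma calls, Foxc1 among them, and 1 of the 8 mesenchymal calls, that of Prrx1, remained. The 5 progenitor genes all kept theirs. The reverse, H3K27me3 in cap mesenchyme alone of these populations, was found at 6 of 19 early differentiating nephron genes, including Wnt4, the signal that starts nephron epithelium, Lhx1 and Pou3f3. It was also found at the ureteric genes Emx2 and Calb1, the latter not at a score of at least 50. Gata3, Tfap2a and Tfap2b, regulators of ureteric epithelium, had both marks in ureteric epithelium but H3K27me3 only in cap mesenchyme. Over all genes, H3K27me3 was present in ureteric epithelium only at 1797 and in cap mesenchyme only at 776, and H3K4me3 in cap mesenchyme only at 1683 and in ureteric epithelium only at 292. With equal list lengths per mark the H3K27me3 counts were 615 and 371, and with a score of at least 50 they were 740 and 714. With H3K27me3 over at least 50% of the window they were 721 and 106, so the size of the excess in ureteric epithelium depends on the calling rule. The H3K4me3 counts moved too. With the upper 50% of each list by score they were 3069 in cap mesenchyme only and 140 in ureteric epithelium only. At equal list length the count in cap mesenchyme only was 1115.

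Any H3K27me3 was found at 2 of 25 nephron progenitor genes in cap mesenchyme, 7 in ureteric epithelium and 14 in stem cells. The 7 in ureteric epithelium lay at percentile 99.985 of random lists, whose median share was 4.0%, but the ureteric bud and epithelial lists lay at percentile 100 there too. In the same order, the counts were 11, 9 and 19 of 27 ureteric bud genes, 10, 9 and 6 of 29 epithelial genes, 3, 10 and 8 of 23 mesenchymal genes, 6, 13 and 15 of 17 renal stroma genes, and 10, 6 and 16 of 19 early nephron genes. They were 3, 8 and 7 of 13 podocyte genes, 3 of 21 tubule transport genes in each population, 7, 6 and 8 of 15 endothelial genes, 0, 1 and 0 of 17 blood genes, and 9, 10 and 7 of 14 neuron and neural crest genes. Transcription factors of other lineages stood at 41, 41 and 40 of 42. Pluripotency genes stood at 11, 10 and 1 of 26, and germ cell genes at 0, 1 and 10 of 19. Signalling lists stood at 1, 6 and 14 of 25 for GDNF, RET and FGF, 10, 12 and 20 of 29 for Wnt, 5, 6 and 14 of 26 for BMP and TGF-beta, 3, 4 and 8 of 17 for Notch, and 4, 7 and 8 of 18 for retinoic acid. The counts were 0, 1 and 1 of 20 glycolysis genes, 0 of 22 cell cycle genes in each population, and 0, 0 and 1 of 18 housekeeping genes. Writers and erasers of the marks stood at 3, 2 and 2 of 25, the 3 in cap mesenchyme lying at percentile 99.575 of random lists. Some of these counts changed with a score of at least 50 in every list, a setting chosen after seeing the data. H3K27me3 was then in cap mesenchyme only at 7 epithelial genes and in ureteric epithelium only at 1, against 3 and 2 with all peaks. The same counts were 8 and 1 for early nephron genes (6 and 2 with all peaks). For ureteric bud genes they were 4 and 0 (4 and 2). No percentile was computed at that setting.

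**Figure D2:**
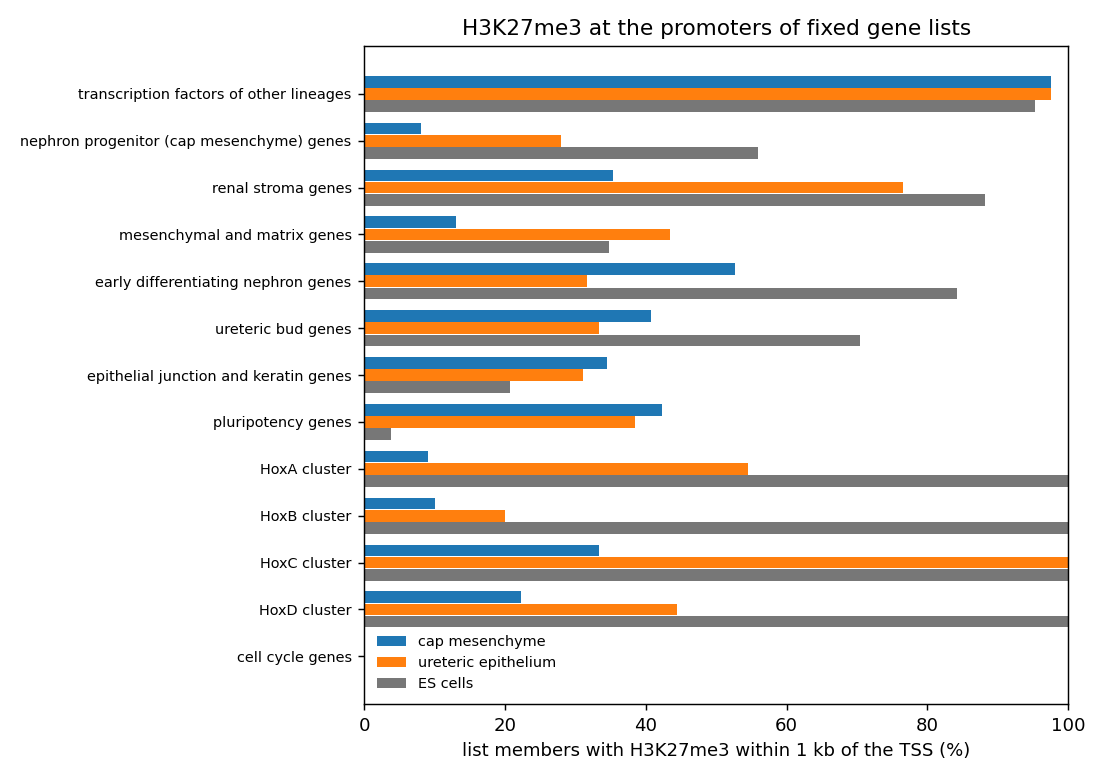
Share of each gene list with H3K27me3 at the promoter, in percent, in cap mesenchyme (MM), ureteric epithelium (UB) and stem cells (mES), 1 sample each. Transcription factors of other lineages carried the mark at 41, 41 and 40 of 42 genes, and nephron progenitor genes at 2, 7 and 14 of 25.

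Markers of other cell types also differed in H3K4me3. The endothelial genes Pecam1, Cdh5, Tek, Tie1, Emcn, Eng and Robo4 had H3K4me3 in ureteric epithelium and neither mark in cap mesenchyme. The podocyte genes Nphs1, which encodes a slit diaphragm protein of the kidney filter, Ptpro and Lmx1b, and the tubule genes Slc34a1, Slc22a6, Cubn and Aqp1, had H3K4me3 in cap mesenchyme and not in ureteric epithelium. So did 19 of 42 transcription factors of other lineages, such as Pax3, Pax7, Hand2 and En2, and 6 of 26 pluripotency genes, including Sox2, Lin28a and Tdgf1. Aqp1 and Slc34a1 are named here after their values were seen. The cap mesenchyme H3K4me3 list was the longer of the pair, which favours calls in cap mesenchyme but not the endothelial calls in ureteric epithelium.

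The 4 Hox clusters, which pattern the body axis, differed in both marks. HoxC (chromosome 15: 102921131 to 103036856) was covered by H3K27me3 over 27.8% of its length in cap mesenchyme, 92.5% in ureteric epithelium and 90.3% in stem cells, and by H3K4me3 over 69.99%, 30.5% and 36.6%. At 6 of 9 HoxC promoters H3K27me3 was found in ureteric epithelium and not in cap mesenchyme. HoxA (chromosome 6: 52155367 to 52260880) was covered by H3K27me3 over 9.51%, 25.3% and 90.2%, and HoxD (chromosome 2: 74668225 to 74765142) over 5.17%, 26.8% and 81.7%. Their H3K4me3 coverage was 70.2%, 69.8% and 52.6%, and 57.6%, 69.3% and 35.9%. HoxB (chromosome 11: 96194316 to 96368254) had little H3K27me3 in either kidney population, 6.98% and 9.50% against 62.3% in stem cells, while H3K4me3 covered 54.6%, 18.2% and 33.5%. Promoters with any H3K27me3 numbered 1, 6 and 11 of 11 in HoxA, 1, 2 and 10 of 10 in HoxB, 3, 9 and 9 of 9 in HoxC, and 2, 4 and 9 of 9 in HoxD, in the same order. At 8 of 10 HoxB genes, including Hoxb5, Hoxb6, Hoxb7 and Hoxb8, H3K4me3 was found in cap mesenchyme and not in ureteric epithelium, although the ureteric bud held 75.8 FPKM of Hoxb7 and 69.2 of Hoxb8.

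**Figure D3:**
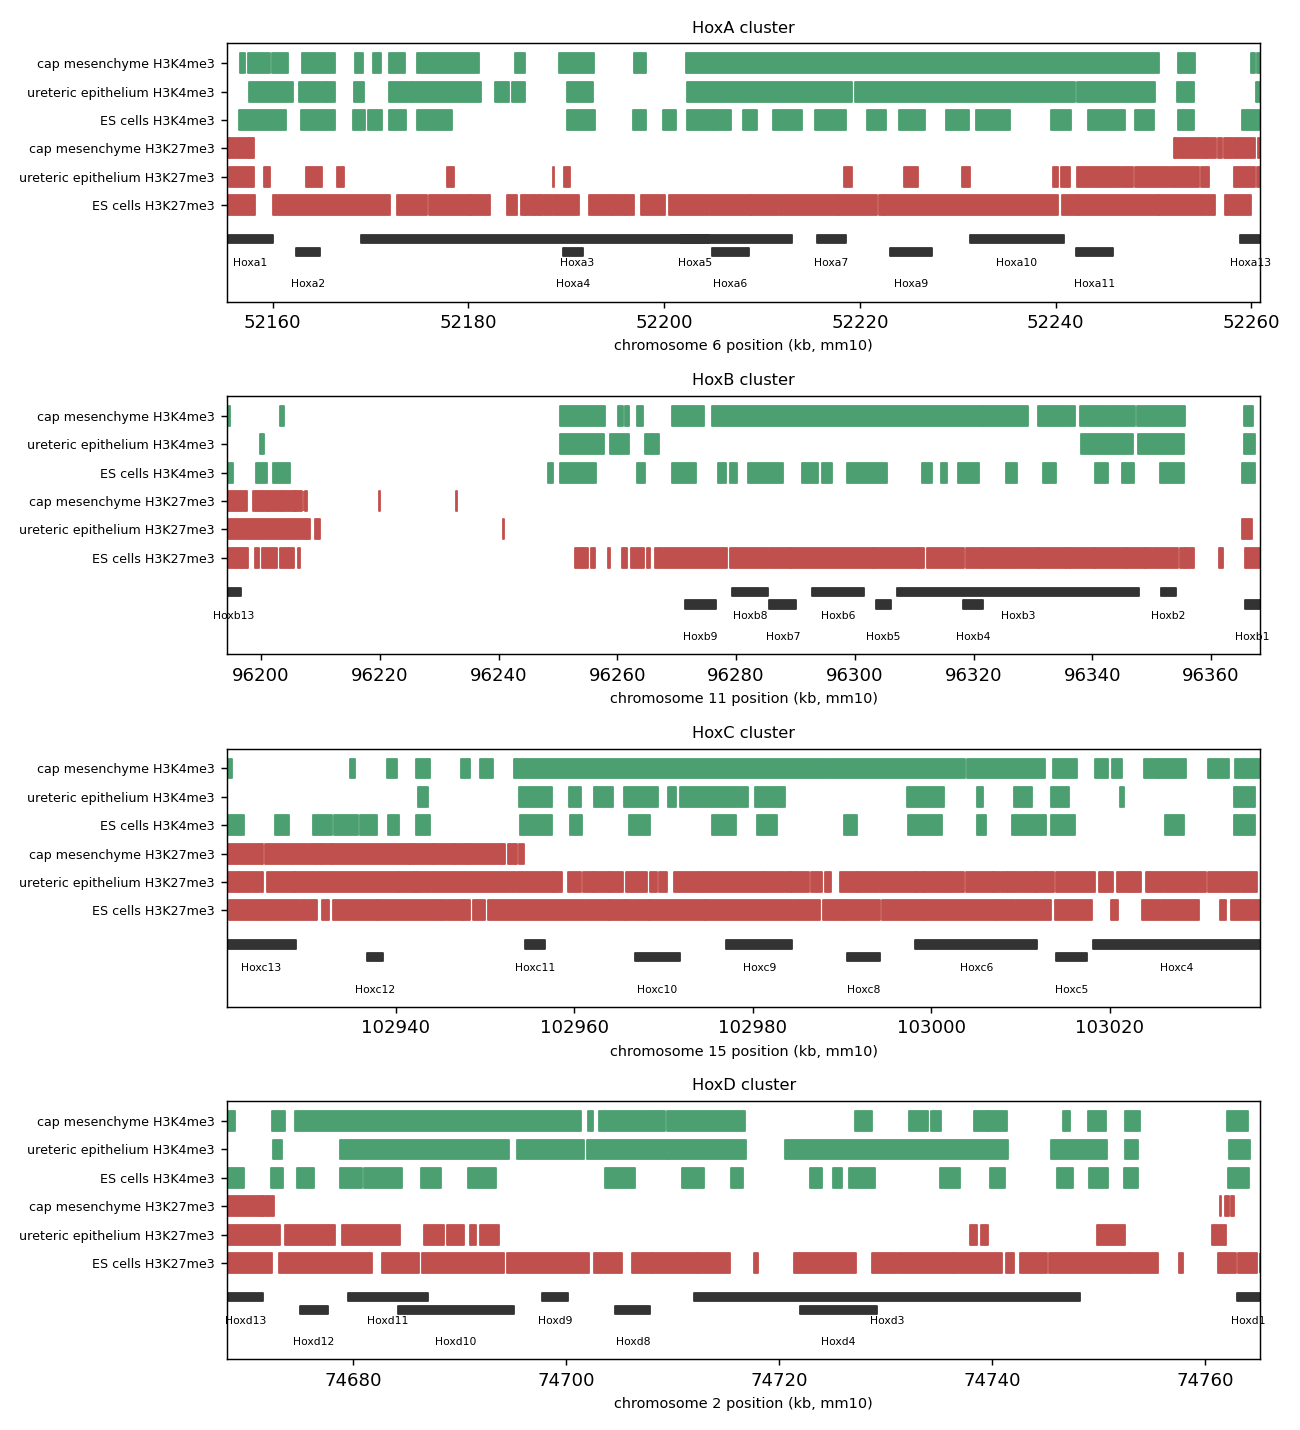
H3K4me3 and H3K27me3 peaks over the HoxA, HoxB, HoxC and HoxD clusters in cap mesenchyme (MM), ureteric epithelium (UB) and stem cells (mES), with mm10 positions on the horizontal axis. H3K27me3 covered 92.5% of HoxC in ureteric epithelium and 27.8% in cap mesenchyme.

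RNA of metanephric mesenchyme and ureteric bud was compared to find the genes that set the 2 tissues apart at the start of kidney development. The genes highest in metanephric mesenchyme by difference included Shisa3 (83.3 against 0.432 FPKM, log2 difference 5.88), Aldh1a2 (101 against 0.901, 5.75), Meis2 (166 against 2.30, 5.67), Cped1 (5.64), Hoxc10 (5.62), Meis1 (5.62) and Vcan (5.58), a matrix proteoglycan. The long noncoding RNA Gm42186 was at 104 FPKM against a listed 0, but this rests on a transcript of 73 bp whose interval in the authors' deposited table ran from 0 to 300.2 FPKM. The genes lowest by the same difference, and so highest in ureteric bud, included Calb1, a calcium-binding protein (0.478 against 1684 FPKM, -10.16), the tight junction gene Cldn6 (-6.92), Rprm (-6.61), Emx2, needed for the ureteric bud to grow (1.43 against 225, -6.54), the splicing factor Esrp1 (-6.46), and the epithelial genes Epcam (-6.28), Cdh1 (-6.17) and Krt8 (-6.11).

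A 4-fold difference was found for 225 genes higher in metanephric mesenchyme and 485 higher in ureteric bud, of 11599 at 1 FPKM or more in either. After rescaling to the same median the counts were 351 and 374, so the excess in ureteric bud depends on the scale. The median difference over 9735 genes at 1 FPKM or more in both was -0.45, and list medians below are to be read relative to it. The long noncoding list is an exception, as its matched random lists had a median of -0.01. Where the authors' deposited intervals of the most abundant transcript of a gene did not overlap, 220 and 475 genes remained. The 4-fold call itself used the sum over transcripts, and these intervals are no replicate check between tissues.

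Nephron progenitor genes were higher in metanephric mesenchyme, with 16 of 25 at least 4-fold higher and a median of 3.57 (95% interval 1.74 to 4.39; random lists -0.47). Examples were Wt1 (5.26), Eya1 (4.96), Uncx (4.81) and Rspo1 (4.75), with Npnt (-5.09) and Bmp7 (-1.59) on the other side. Renal stroma genes had a median of 3.89 (1.62 to 5.08), with 11 of 17 at least 4-fold higher, such as Foxc1 (5.22), and Smoc2 (-1.65) on the other side. Mesenchymal and matrix genes had a median of 2.56 (1.61 to 4.09), with 13 of 19 used at least 4-fold higher, including Cdh11 (5.41) and Col3a1 (4.78). Ureteric bud genes were higher in ureteric bud, 23 of 26 at least 4-fold, with a median of -3.97 (-4.38 to -2.56) and Ret (-5.78) and Gata3 (-5.27) among them. Epithelial genes had a median of -4.89 (-5.62 to -3.51), with 26 of 27 at least 4-fold. Early nephron genes had a median of -1.69 (-3.51 to 0.66), with Pou3f3 (-5.58), Lhx1 (-4.20) and Ccnd1 (-3.51) higher in ureteric bud, and Wnt4 (1.72) and Fgf8 (1.62) higher in metanephric mesenchyme. Of the 19 genes on that list, 11 are also on other lists.

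Beside these, some markers of other cell types were higher in the dissected metanephric mesenchyme, though the intervals of the blood and of the neuron and neural crest lists spanned 0. Members at least 4-fold higher there numbered 3 of 13 endothelial, 3 of 7 blood and 2 of 7 neuron and neural crest genes used. In each of these lists 0 members were 4-fold higher in ureteric bud. Endothelial genes had a median of 1.44 (0.93 to 2.12; random lists -0.34), with Kdr (8.87 against 0.868 FPKM) and Cdh5 (7.97 against 0.760). Embryonic haemoglobins of the blood list were at 61.6 against 4.02 FPKM for Hba-x and 74.5 against 10.9 for Hbb-y, in a list with a median of 1.18 (-0.70 to 3.64). Neuron and neural crest genes had a median of 1.69 (-0.91 to 3.17), with Isl1 (3.17), Stmn2 (2.08) and Dbh (2.24 FPKM against a listed 0), and Tubb3 (-0.91) on the other side.

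HoxC genes were higher in metanephric mesenchyme (median 4.16, 2.29 to 5.62; all 7 used were at least 4-fold higher), as were HoxA genes (2.37, 1.09 to 3.84), with Hoxa10 (4.48), Hoxa6 (3.84), Hoxa11 (3.57) and Hoxa9 (3.50). HoxD was split, with Hoxd10 (5.29) and Hoxd11 (4.49) higher in metanephric mesenchyme and Hoxd1 (-2.51) and Hoxd8 (-2.46) higher in ureteric bud, so its median of -0.38 turned to 0.12 after rescaling. HoxB had a median of -0.77 (-2.81 to -0.46), with Hoxb8 (-2.97) and Hoxb7 (-2.81) lowest and Hoxb1 (1.54) on the other side. Podocyte genes had a median of 0.99 (-0.68 to 3.89), led by Foxc2 (3.89) and Lmx1b (3.22). The 4 tubule transport genes used had a median of -2.05 (range -10.16 to -1.44), the 7 pluripotency genes one of -1.79 (-4.13 to -0.30), led by Tfcp2l1 (-4.13) and Sall4 (-2.43), and the 5 transcription factors of other lineages one of 1.5 (range -2.65 to 3.17). Of 19 germ cell genes only 1, Dmc1 (2.5 against 0.144 FPKM), was high enough to be used.

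Glycolysis genes had a median of -1.61 (-1.84 to -1.45) and of -1.11 after rescaling, below every random list, with 2 of 20 at least 4-fold lower in metanephric mesenchyme. The list included Slc2a3 (-3.20), Slc2a1 (-2.86), the glucose transporters, and Ldha (-1.90), with Pfkp (0.25) on the other side. Cell cycle genes (-0.41, -0.65 to -0.12) and writers and erasers of the marks (-0.27, -0.44 to -0.01) had no member 4-fold different, and both turned direction after rescaling, to 0.11 and 0.26. Housekeeping genes stood at -0.71 (-0.88 to -0.35) and -0.15 after rescaling. GDNF, RET and FGF signalling had a median of -1.29 (-2.56 to 0.98), with Gfra1 (-3.94), Fgfr4 (-3.26) and Spry1 (-3.22) on the ureteric side and Gdnf (3.46) and Fgf10 (2.29) on the mesenchymal side. Wnt signalling stood at -0.84 (-1.94 to 0.38), with Tcf7 (-4.26) and Wnt11 (-3.85) against Rspo3 (4.18), and Wnt6 and Wnt9b were listed at 0 in metanephric mesenchyme. The medians of BMP and TGF-beta (-0.31, 0.21 after rescaling), Notch (-0.22, 0.29) and retinoic acid genes (-0.16, 0.29) lay at percentiles 84.1, 81.8 and 97.9 of random lists, and their intervals before rescaling spanned 0. Their members went both ways, as with Bmper (3.62) and Id4 (-2.35), Hey2 (1.54) and Jag1 (-2.96), and Crabp1 (4.83) and Aldh1a3 (-5.67).

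**Figure D4:**
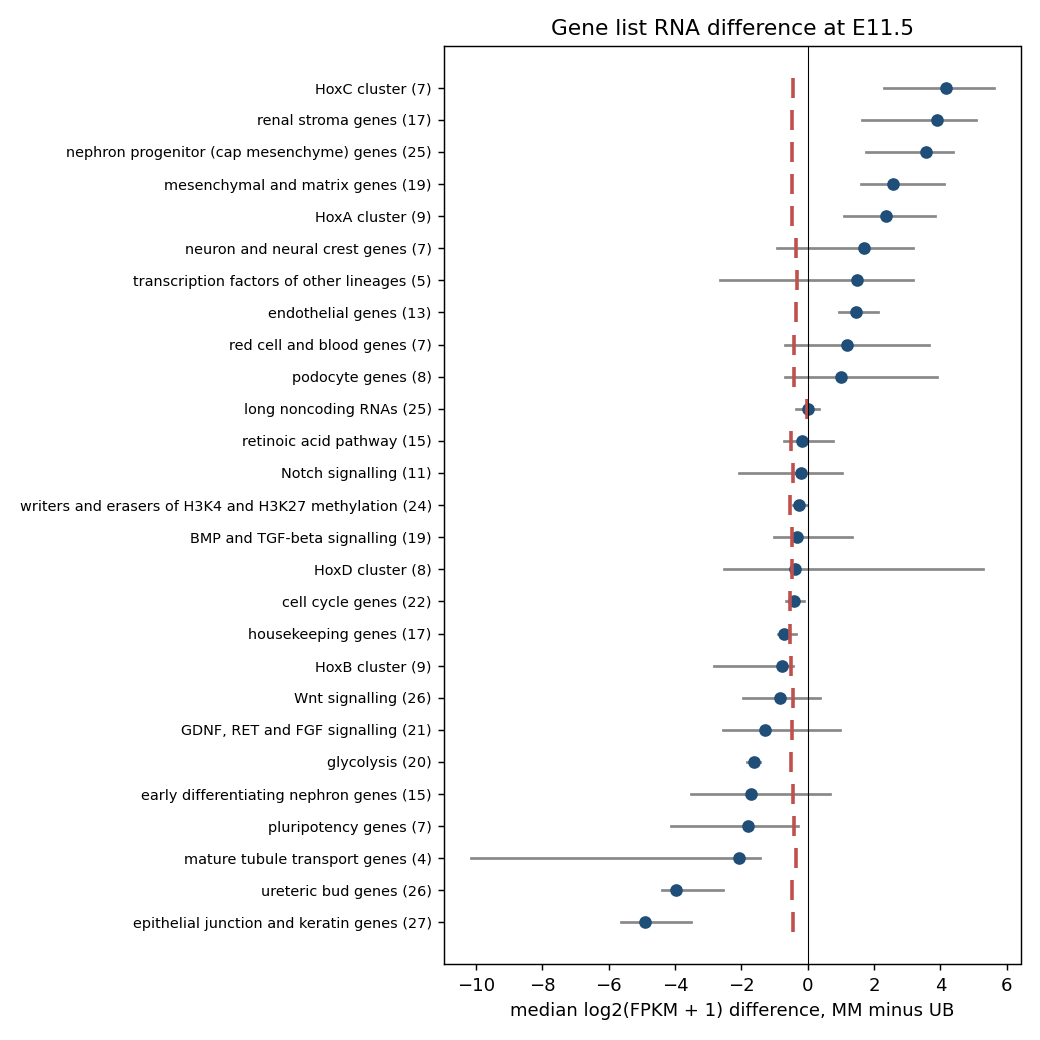
Median difference in log2(FPKM + 1), metanephric mesenchyme minus ureteric bud, per gene list, with its 95% order-statistic interval over genes (range for lists under 6 members), the number of genes used, and a dash at the median of 10000 matched random lists. The HoxC list stood highest at 4.16 and the epithelial list lowest at -4.89, while the lists for HoxD, BMP and TGF-beta, Notch, retinoic acid, cell cycle, writers and erasers, and long noncoding RNAs changed direction after rescaling.

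Finally the marks were set beside RNA, bearing in mind that the stages differ. Marks of cap mesenchyme were paired with RNA of metanephric mesenchyme, and marks of ureteric epithelium with RNA of ureteric bud. Genes with H3K4me3 only were at 1 FPKM or more in 66.0% of cases in the mesenchymal pair and 73.2% in the ureteric one, those with both marks in 14.5% and 22.7%, those with H3K27me3 only in 3.54% and 4.17%, and those with neither in 4.67% and 5.16%. Where H3K27me3 was in ureteric epithelium only, 63 genes were at least 4-fold higher in metanephric mesenchyme and 31 in ureteric bud, with a median of 0.10 over 394 genes (-0.09 to 0.38; random lists -0.41), which became 0.63 after rescaling and ranged from -0.20, with promoters of 2500 bp on each side, to 1.09, with H3K27me3 over at least 50% of the window. Examples were Aldh1a2, Foxd2os, Hoxc10, Meis1 and Vcan, of which Aldh1a2 and Meis1 had ureteric H3K27me3 peaks under the median score of their list, but Mal2 (-5.83) and Epcam (-6.28) had the mark and the higher RNA in the ureteric populations. Where H3K27me3 was in cap mesenchyme only, the median was -0.88 over 170 genes. It was -0.31 after rescaling and -2.87 with H3K27me3 over at least 50% of the window. Of the 170 genes, 3 were at least 4-fold higher in metanephric mesenchyme and 38 in ureteric bud. These included Emx2, Rprm and Pou3f3. Where both populations had H3K27me3 the median was also low, at -0.73 (28 against 58) and -0.050 after rescaling. H3K4me3 in cap mesenchyme only went with a median of -0.11 over 221 genes (25 against 15), including Des (4.81) and Meox1 (4.15), and the median became 0.43 after rescaling. H3K4me3 in ureteric epithelium only went with -1.0 over 78 genes (5 against 21), including Cldn8 (-5.67), a median that became 0.12 after rescaling. The rescaling factor adds at most 0.559 to a log2 difference, so this change also came from genes that newly passed 1 FPKM. Of the 225 genes higher in metanephric mesenchyme, 91 (40.4%) had H3K27me3 in ureteric epithelium and 31 (13.8%) in cap mesenchyme. Of the 485 genes higher in ureteric bud, 96 (19.8%) had it in cap mesenchyme and 89 (18.4%) in ureteric epithelium.

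Long noncoding RNAs were examined in the same way. Pantr1 (-4.19), Rmst (-3.94) and Lhx1os (7.25 FPKM in ureteric bud, listed at 0 in metanephric mesenchyme) were higher in ureteric bud, and Dnm3os (3.63) and Hoxa11os (3.51) in metanephric mesenchyme. Pantr1, Pantr2 and Lhx1os, neighbours of Pou3f3 and Lhx1, had H3K27me3 in cap mesenchyme and not in ureteric epithelium. The fixed list of 40 had 25 members with enough RNA and a median of -0.01 (-0.36 to 0.35; random lists -0.01; 0.51 after rescaling). It lay at percentile 56.0 of random lists, and at 49.5 after rescaling. H3K27me3 was at 12, 11 and 13 of 36 promoters of the list in cap mesenchyme, ureteric epithelium and stem cells. Of 12727 long noncoding genes, 3338 had H3K4me3 in cap mesenchyme, 2804 in ureteric epithelium and 4473 in stem cells, with 241 in cap mesenchyme alone and 71 in ureteric epithelium alone. A 4-fold difference was found for 18 higher in metanephric mesenchyme and 19 higher in ureteric bud.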

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

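Of the tests in this part, those of missing peaks and of an unmarked cluster at HoxB, and that of endothelial promoters being marked in ureteric cells, were chosen only after the result was seen, and so was the rule that a whole interval must lie past a predicted bound.

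HoxB and HoxC drew attention because the 2 kidney populations departed from stem cells in opposite directions. H3K4me3 over HoxB was 21.1 percentage points higher than in stem cells in cap mesenchyme and -15.2 points in ureteric epithelium, a gap of 36.3. H3K4me3 over HoxC stood at 33.3 and -6.11 points, a gap of 39.5, and H3K27me3 over HoxC at -62.5 and 2.16 points, a gap of -64.6. With 1 sample per group these differences were not tested. Among 1245 antisense transcripts, which the comparisons leave out, 99 were at least 4-fold higher in metanephric mesenchyme and 78 in ureteric bud.

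In the ureteric H3K4me3 list no peak lies in 71.2 kb of HoxB (chromosome 11: 96267004 to 96338177), which holds the starts of 7 genes from Hoxb3 to Hoxb9, while H3K4me3 covers 64.9 kb of it in cap mesenchyme and 33.7 kb in stem cells. Peaks removed from the list after it was numbered are argued against, because the numbering of the ureteric peaks skips 0 numbers. Peaks lost before numbering would leave no skip, so the numbering cannot speak to them. A cluster unmarked in ureteric cells stays open, since the 7 genes had a median of 29.1 FPKM in ureteric bud (11.6 in metanephric mesenchyme), but at E11.5 and not at E15.5. The reporter used for the sort carries a Hoxb7 promoter. Transgene copies raising the control could hide peaks of both marks, but only over the stretch that they carry. How much of the 71.2 kb that is was not examined. H3K27me3 covers 0 kb there in ureteric epithelium, but also 0 kb in cap mesenchyme, so these explanations cannot be told apart.

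The endothelial genes Pecam1, Cdh5, Tek, Tie1, Emcn, Eng and Robo4, picked as those with H3K4me3 in ureteric epithelium and not in cap mesenchyme, form 7 of a list of 15, of which 1 (Sox17) is on another list. The shorter ureteric peak list could not produce this direction. Endothelial cells among the sorted ureteric cells, which the Hoxb7-GFP gate should remove, would give weak peaks, with a median score percentile under 25 among ureteric promoter peaks. The median was 59.4, past the bound of 50 set in advance against this source, but its interval of 22.2 to 90.0 spans both bounds, so this source may still contribute. That ureteric cells mark these promoters is not settled either, as the median of 0.397 FPKM in ureteric bud comes from an earlier stage, and the most abundant of the 7 in these libraries, Cdh5, was at 0.760 FPKM there and 7.97 in metanephric mesenchyme.

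The 8 podocyte and tubule genes with H3K4me3 in cap mesenchyme and not in ureteric epithelium included Nphs1, Ptpro, Lmx1b, Slc34a1, Slc22a6, Cubn and Aqp1, and 1 gene of each list is on another list. The longer cap mesenchyme list is argued against as the cause, because 8 of these 8 genes kept the mark at equal list length. Differentiated nephron cells among the sorted cells, which the Cited1-RFP gate should remove, could leave weak peaks, and the median score percentile was 8.44, under the bound of 25 set in advance. Its interval of 5.98 to 82.1 spans that bound, the upper end being Lmx1b, which was also at 8.99 FPKM in metanephric mesenchyme. Weak marking in the progenitors themselves would give the same low scores and was not tested.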

How the results depend on the processing

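Chosen only after the data were seen were the settings with a score of at least 50 in every list, both ends of every gene, and those without Hoxb3 to Hoxb9 or without the endothelial, blood and neural crest lists. Of the values that answer a comparison, 400 stayed within their interval or within 1.5 times their count, and 158 moved further. Some of the 400 could not move. They include 27 list medians under random lists without matching, since a list median does not use the random lists. They also include the 4-fold counts with no filter on low values, since a difference of 2 already requires more than 2 FPKM. Another 4, all with an interval that excluded 0, changed direction. A sign change of a median whose interval spanned 0 was not counted as a change of direction. Counted over all values and settings, 16 changed sign, 10 of them under rescaling, and in 12 of the 16 the interval spanned 0. Of the other values 910 stayed and 191 moved. No paired analysis was possible because each group holds 1 sample. A setting with only the most upstream start per gene was not run, since it equals the one used for genes with a strand and is undefined for the others. Read depth of the peak lists is unknown, so differences between lists in peak number, and counts resting on weak H3K27me3 peaks, have no depth correction. Germ cell genes gave no RNA median. Unless a setting's construction shows it (wider windows, fewer or merged peaks), the cause was not tested.

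With promoters of 500 bp on each side, H3K4me3 peaks lay at promoters in 42.0% (cap mesenchyme), 54.0% (ureteric epithelium) and 23.4% (stem cells), and H3K27me3 peaks in 2.41%, 1.90% and 22.2%. Both marks in stem cells and in ureteric epithelium were found at 770 genes. Shares at 1 FPKM or more were 12.3% and 18.1% with both marks and 5.49% and 5.98% with neither, in the mesenchymal and ureteric pairs of marks and RNA. The median RNA difference where H3K27me3 was ureteric only was 0.48.

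With 2500 bp on each side the promoter shares were 48.4%, 60.6% and 28.9% for H3K4me3 and 8.28%, 5.95% and 49.8% for H3K27me3, in the same order. Both marks were found at 2686 genes in cap mesenchyme and 2903 in ureteric epithelium, and H3K27me3 only at 1314 and 2713. H3K27me3 in cap mesenchyme and not ureteric epithelium stood at 1243 and the reverse at 2859. Shares at 1 FPKM or more in the mesenchymal pair were 65.1% with H3K4me3 only, 22.1% with both, 2.16% with H3K27me3 only and 3.59% with neither, and in the ureteric pair 31.7% with both and 3.98% with neither. The median RNA difference where H3K27me3 was ureteric only became -0.20.

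With the upper 50% of each list by score, promoter shares were 75.1%, 82.7% and 41.3% for H3K4me3 and 5.87%, 4.01% and 42.7% for H3K27me3. Both marks were found at 1054, 599 and 2040 genes in cap mesenchyme, ureteric epithelium and stem cells, and H3K27me3 only at 480 in stem cells. Of genes with both marks in stem cells, 1097 had H3K4me3 only, 634 both and 244 H3K27me3 only in cap mesenchyme, against 632, 323 and 723 in ureteric epithelium, where 362 had neither. H3K4me3 was found in cap mesenchyme and not ureteric epithelium at 3069 genes and the reverse at 140, and at 1809 long noncoding genes in ureteric epithelium. Shares at 1 FPKM or more were 70.8% with H3K4me3 only and 5.11% with neither in the mesenchymal pair, and 80.7% with H3K4me3 only, 28.8% with both, 7.35% with H3K27me3 only and 9.02% with neither in the ureteric pair. Median RNA differences were -1.24 where H3K27me3 was in cap mesenchyme only and 0.38 where it was ureteric only. Shared H3K4me3 peaks were 70.5% (cap mesenchyme in ureteric epithelium), 90.2% (cap mesenchyme in stem cells) and 94.9% (ureteric epithelium in stem cells), and shared H3K27me3 peaks 35.5%, 9.25% and 4.64%.

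At equal list length per mark, H3K4me3 peaks lay at promoters in 56.9% in cap mesenchyme and 51.2% in stem cells, and H3K27me3 peaks in 14.4% in cap mesenchyme and 11.8% in ureteric epithelium. Both marks were found at 980 genes in cap mesenchyme and 879 in ureteric epithelium, and H3K27me3 only at 308, at 653 and, in stem cells, at 1202. Of genes with both marks in stem cells, 592 had both and 71 H3K27me3 only in cap mesenchyme, and 518 and 211 in ureteric epithelium. H3K4me3 in cap mesenchyme and not ureteric epithelium stood at 1115, H3K27me3 likewise at 371 and the reverse at 615, and H3K4me3 lay at 2810 long noncoding genes in stem cells. Shares at 1 FPKM or more were 12.2% with both marks in the mesenchymal pair, and 70.6% with H3K4me3 only and 14.7% with both in the ureteric pair. Median RNA differences were -1.48 (H3K27me3 in cap mesenchyme only) and 0.78 (ureteric only). Shared peaks were 79.5%, 63.9% and 64.1% for H3K4me3 and 42.8%, 32.2% and 21.0% for H3K27me3, in the order of pairs given above.

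With reciprocal overlap of at least 50% of both peaks, shared H3K4me3 peaks were 57.8%, 53.4% and 58.6% and shared H3K27me3 peaks 13.0%, 1.27% and 1.36%. With H3K27me3 peaks merged within 3 kb they were 48.7%, 4.59% and 3.72%. With H3K27me3 over at least 50% of the window, both marks were found at 602, 771 and 1358 genes in cap mesenchyme, ureteric epithelium and stem cells, and H3K27me3 only at 159, 605 and 78. Of genes with both marks in stem cells, 848 had H3K4me3 only, about 4.0e+02 both, 76 H3K27me3 only and 30 neither in cap mesenchyme, against 559, 427, 303 and 69 in ureteric epithelium. H3K27me3 was found in cap mesenchyme and not ureteric epithelium at 106 and the reverse at 721, with median RNA differences of -2.87 and 1.09. With a score of at least 50 in every list, H3K27me3 only was found at 511 genes in cap mesenchyme and 847 in ureteric epithelium, both marks at 1157 in ureteric epithelium, and H3K27me3 in ureteric epithelium only at 740 (714 in cap mesenchyme only). Of the list genes with H3K27me3 in ureteric epithelium only, 1 of 8 mesenchymal, 4 of 7 renal stroma, 5 of 5 nephron progenitor and 6 of 6 HoxC genes kept the call. Median RNA differences were then -1.22 (H3K27me3 in cap mesenchyme only) and 0.67 (ureteric only).

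With the most abundant transcript per gene, shares at 1 FPKM or more were 60.1% with H3K4me3 only, 12.1% with both and 4.03% with neither in the mesenchymal pair, and 69.7%, 20.5% and 4.57% in the ureteric pair. With a pseudocount of 0.1, about 4.0e+02 and 784 genes differed 4-fold, and medians were -0.55 where both populations had H3K4me3, -1.06 where H3K27me3 was in cap mesenchyme only and -0.99 where both had it. List medians were then 5.62 (nephron progenitor), -4.95 (ureteric bud), -7.11 (epithelial), 5.54 (renal stroma), 2.59 (endothelial), 4.0 (neuron and neural crest), 4.27 (transcription factors of other lineages) and 6.06 (HoxC). With a pseudocount of 0.5 the epithelial median was -5.66. With no filter on low values the medians of the tubule and pluripotency lists were 0, because most members are at or near 0, and with 5 FPKM in the higher library the endothelial median was 2.24.

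Rescaling to the same median changed the sign of 4 values whose interval excluded 0: H3K4me3 in ureteric epithelium only (0.12), H3K4me3 in both (0.019), cell cycle genes (0.11) and writers and erasers of the marks (0.26). The filter at 1 FPKM was applied after rescaling, so the genes in a set could also change. The rescaling factor itself adds at most 0.559 to a log2 difference. It cannot alone take H3K4me3 in ureteric epithelium only from -1.0 to 0.12. Nor can it alone take H3K27me3 in cap mesenchyme only from -0.88 to -0.31, or in both from -0.73 to -0.050. Genes that newly passed the filter thus shaped these values, and how much each step added was not tested. Signs also changed for medians whose interval spanned 0, to 0.12 (HoxD), 0.21 (BMP and TGF-beta), 0.29 (Notch), 0.29 (retinoic acid) and 0.51 (long noncoding RNAs). The same held where H3K4me3 was in cap mesenchyme only, to 0.43. Rescaling also gave -0.31 where H3K27me3 was in cap mesenchyme only, 0.63 where it was ureteric only and -0.050 where it was in both. It gave 351 genes at least 4-fold higher in metanephric mesenchyme, and list medians of -0.24 (HoxB), -1.11 (glycolysis) and -0.15 (housekeeping).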

Other observations

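Several genes of signalling between the 2 kidney lineages, a receptor among them, differed in RNA without a matching difference in marks. Here and in the next paragraph the RNA is from E11.5 and the marks from E15.5 (ureteric epithelium) and E18.5 (cap mesenchyme). Each gene with a strand was scored at 1 start only. Gdnf had H3K4me3 only in both kidney populations and both marks in stem cells, although its RNA was at 10.8 FPKM in metanephric mesenchyme and 0.0752 in ureteric bud. Ret also had H3K4me3 only in both, with 0.341 and 72.8 FPKM. Wnt9b, the ureteric signal that induces nephrons, was listed at 0 in metanephric mesenchyme and at 16.5 FPKM in ureteric bud, yet had H3K27me3 only in ureteric epithelium and both marks in cap mesenchyme. By contrast, Bmper, a modulator of BMP signalling, and Rspo3, an amplifier of Wnt signalling, had H3K27me3 in ureteric epithelium and not in cap mesenchyme and were at 11.9 against 0.0525 and 17.4 against 0.0155 FPKM. With a score of at least 50 in every list, a setting chosen after seeing the data, Bmper kept this difference in H3K27me3 and Rspo3 did not.

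Among epithelial genes the marks followed RNA in some cases and not in others. Cldn3, an epithelial junction gene, had both marks in cap mesenchyme and H3K4me3 only in ureteric epithelium, with 0.0920 and 59.8 FPKM, but Krt7 had H3K4me3 in cap mesenchyme and neither mark in ureteric epithelium, with RNA listed at 0 and at 24.9 FPKM. Cdh1 and Esrp1 had both marks in both kidney populations and H3K4me3 only in stem cells, with 72.2 and 90.6 FPKM in ureteric bud, but at a score of at least 50 the H3K27me3 of Cdh1 was left in cap mesenchyme only. Of the 33 widest H3K4me3 peaks of cap mesenchyme, 2 had no ureteric H3K4me3 peak, the one over HoxB and one of 10.7 kb at Fcgr3 (chromosome 1: 171063424 to 171074165), where the ureteric H3K27me3 list has its peak of 22.6 kb. Fcgr3, which encodes an immune cell receptor, is the only protein-coding or long noncoding gene listed there, and other gene types were not looked at. The input libraries were not analysed, so whether these peaks concern Fcgr3 was not tested.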
